A study of Mus musculus with 24 samples.

How the data were processed

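Gene expression was measured by 24 single-colour arrays, 20 of mouse jejunum and 4 of CMT93 cells, each from biotin-labelled total RNA on an Affymetrix array, per the labels. The deposited values are log2 intensities per transcript cluster, with 1 column per array and no pooled columns. The log2 scale was read from the values, which run from 1.83 to 19.5. The background correction, summarisation and normalization the authors used are not given in the sources used here. The array medians lay between 6.49 and 6.85. Because array data carry no read depth, the number of arrays limits the precision.

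The table held 28846 features, of which 6640 were spike-in, background or normalisation controls and 22206 were transcript clusters. The platform annotation paired 19572 of the clusters with exactly 1 gene symbol and 0 with several, and the remaining 2634 are not named here. All 19572 Entrez identifiers were found in the gene table of the mouse reference, and 0 symbols needed an update. For the 55 symbols with more than 1 cluster, the cluster with the highest mean over the arrays of the fit was kept, which left 19505 genes. No value was missing, 0 pairs of arrays were identical and 0 columns of values went unused. No genome build is named for the arrays, so no coordinates are given.

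All choices of groups, tests, gene lists and alternatives were made before the data were examined, except those said to have been chosen later. The labels put 5 mice in each of 4 groups and 2 cultures in each of the cell groups. The mice are separate animals. For the cell cultures nothing states that they were independent, so their p-values measure only the spread between these samples, which may be technical. The 20 jejunum arrays were fitted in limma 3.58.1 (R 4.3.3) with 4 group means and no covariate, using lmFit, contrasts.fit and eBayes with default settings. The 4 cell arrays were fitted apart, with 2 residual degrees of freedom. Benjamini-Hochberg adjusted p-values below 0.05 over the 19505 genes were called, without a limit on fold, and every adjusted p for a gene comes from limma. The 8 comparisons were infection in mice with and without cinnamaldehyde, cinnamaldehyde in mice with and without infection, both factors averaged over the other, their interaction and cinnamaldehyde in cells.

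The 44 gene lists, fixed beforehand, were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Counts adjusted over the list alone apply the same adjustment to the members of 1 list. An adjusted p quoted for a list comes from camera at the preset correlation unless said otherwise. Of all the list calls across the jejunum comparisons, those of the mast cell and circadian clock lists in mice without cinnamaldehyde, and those of the mast cell and alternatively activated macrophage lists in cinnamaldehyde mice and in the average of both diets, held with the estimated correlation.

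Genes named in the text follow a fixed rule. For each comparison these are the 10 largest rises and the 10 largest falls past the threshold, up to 4 members with the smallest p of each list that passed or held a called gene, and, where fewer than 10 genes were called, the 5 rises and 5 falls with the smallest unadjusted p as values. Predicted, clone-based and small RNA symbols and immune receptor segments were left out of the ranking. Not every gene the rule takes is described, and calls that depended on most single arrays were largely left out.

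Dim genes have only a bound. A gene was taken as not above background in a group when it lay below the median of the negative controls on every array of that group. For such genes the fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of that median and the gene's own value.

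Signature scores are the mean of the genes that rose minus the mean of those that fell, each gene centred over the jejunum arrays. They were compared by exact two-sided permutation tests of 5 against 5 mice, whose smallest possible p is 0.00794, and for differences of differences by a permutation test with 100000 draws. The 7 signature tests were adjusted as 1 family. The cell line signature used the 50 largest rises and the 50 largest falls in cells regardless of threshold.

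The fits were tested on simulated data with 200 of 19505 genes changed by a log2 of 1, 2 or 4. Noise was drawn independently for each gene, so genes that vary together and outlying arrays were not simulated. The shares below hold for that setting and may overstate recovery in the real data. At a log2 change of 1 the share of changed genes recovered was 67.2% for infection in mice without cinnamaldehyde, 65.7% in cinnamaldehyde mice, 79.1% for cinnamaldehyde in uninfected mice, 55.2% in infected mice, 91.0% and 95.5% for the averaged infection and cinnamaldehyde effects, 16.4% for the interaction and 19.4% for the cells. At a log2 change of 2 the lowest share was 95.5%, for the interaction. The shifted list ranked 1 each time, though with genes that varied independently, and 0 called genes had the wrong direction. Calls outside the changed genes and that list ran from 7, for cinnamaldehyde in uninfected mice, to 16, for averaged infection. In cells they made up 15 of 166 calls.

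Alternatives were quantile normalization again, centring each array, averaging probes, leaving out dim genes, unnamed clusters kept, a fold limit of 1.5, eBayes with trend and robust settings, array weights, the replicate number as a block, covariates for smooth muscle and enterocyte content, fits on only the groups compared or on all 24 arrays, and each array left out in turn. A further 5, for clock phase, hybridisation controls and narrower cell line signatures, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were joined with pandas 2.3.3 and numpy 2.4.6.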

Results

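The series asks how a dietary compound alters the response of the small intestine to a parasitic worm. Jejunum, the middle part of the small intestine, was taken from C57BL/6 mice in 4 groups of 5: uninfected controls, mice infected with 200 larvae of the nematode Heligmosomoides polygyrus for 14 days (Hp), mice given cinnamaldehyde, the main aroma compound of cinnamon, for 21 days (CA), and mice given both (HpCA). CMT93 cells, a mouse rectal carcinoma epithelial line, were compared with and without cinnamaldehyde at 5 µg/mL for 5 h, with 2 cultures each. Values are log2 intensities, and differences are on that scale with their standard errors.

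The 20 jejunum arrays correlated with each other between 0.966 and 0.993 across transcript clusters, and the 4 cell arrays between 0.984 and 0.991. The array of CA replicate 5 stood apart, with correlations between 0.966 and 0.979 to the other jejunum arrays, while the lowest among the rest was 0.972. Its hybridisation controls averaged 12.4, against 11.7 on the next highest jejunum array. Across groups these spiked controls averaged 10.4 ± 0.06 in controls, 10.9 ± 0.42 in Hp, 11.02 ± 0.80 in CA and 11.1 ± 0.38 in HpCA (SD, n = 5 each), so they differed between groups as well as arrays.

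Infection in mice without cinnamaldehyde raised genes of mucosal mast cells, the granulocytes that expand in the gut wall during worm infection. Mcpt1, a chymase of mucosal mast cells, averaged 15.9 ± 0.70 in Hp and 7.32 ± 0.84 in control mice (SD, n = 5 each), a rise of 8.54 ± 0.50 (SE, adjusted p = 6.4e-10), and each of the 5 Hp mice lay above each control. Mcpt2 and Cpa3, a granule carboxypeptidase, lay below background in controls and were at least 61.5-fold and at least 28.8-fold higher in Hp mice. Of the 18 measured members of the mast cell list, 7 rose and 11 did not pass, and 9 rose when adjusted over the list alone (list adjusted p = 6.6e-19; adjusted p = 0.0304 with an estimated correlation). Cma2 and Mcpt4, further chymases, and Ms4a2, a chain of the high-affinity IgE receptor, also lay below background in controls. They were at least 2.61-fold, at least 3.79-fold and at least 1.23-fold higher (adjusted p = 0.0012, 0.0017 and 5.2e-05).

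Tuft cells are epithelial sensors of worms, and their list of 18 genes had a median difference of 1.497 (adjusted p = 2.5e-14), with 0 members past the threshold over all genes and 13 when adjusted over the list alone. With an estimated correlation the list did not pass (adjusted p = 0.217). Its members Dclk1, a tuft cell kinase, and Il17rb, the IL-25 receptor, did not pass. Dclk1 differed by 2.01 ± 0.55 (adjusted p = 0.14), and Il17rb, below background in control mice, was at least 2.55-fold higher (adjusted p = 0.062). Alox5ap, which takes part in leukotriene synthesis, differed by 1.63 ± 0.44 (adjusted p = 0.13). Without HpCA replicate 3 the adjusted p was 0.022 for Il17rb and 0.014 for Alox5ap, and Il17rb also passed without Hp replicate 1 (0.044), Hp replicate 5 (0.033) or HpCA replicate 2 (0.036).

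**Figure D1:**
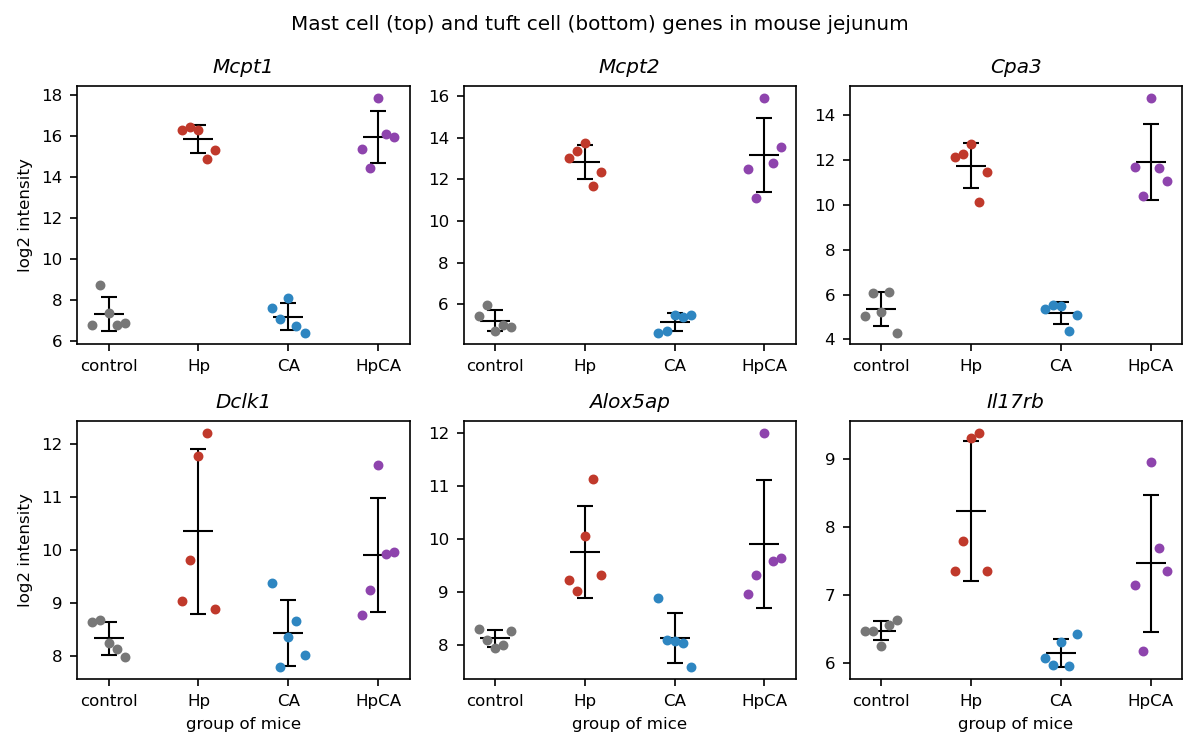
Log2 intensity of the mast cell genes Mcpt1, Mcpt2 and Cpa3 and the tuft cell genes Dclk1, Alox5ap and Il17rb in jejunum, 1 point per mouse, with bars for the mean and SD of 5 mice per group (control, Hp, CA, HpCA). The mast cell genes of all infected mice lie above those of all uninfected mice, while the tuft cell genes spread widely among infected mice.

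Genes of the circadian clock, the cell's timekeeping loop, also changed with infection in mice without cinnamaldehyde. Of 17 measured members, 7 rose, 3 fell and 7 did not pass, with 11 and 3 when adjusted over the list alone (list adjusted p = 5.1e-09; adjusted p = 0.0304 with an estimated correlation). Dbp, an output factor of the clock, rose by 3.87 ± 0.36 (adjusted p = 1.2e-06), and the repressors Per3 and Per2 rose by 2.34 and 2.32. Arntl, which encodes the activator BMAL1, fell by 2.70 (SE 0.23, adjusted p = 4.5e-07). Of the 7 that rose, Tef lay below background in both groups and Ciart in control mice.

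**Figure D2:**
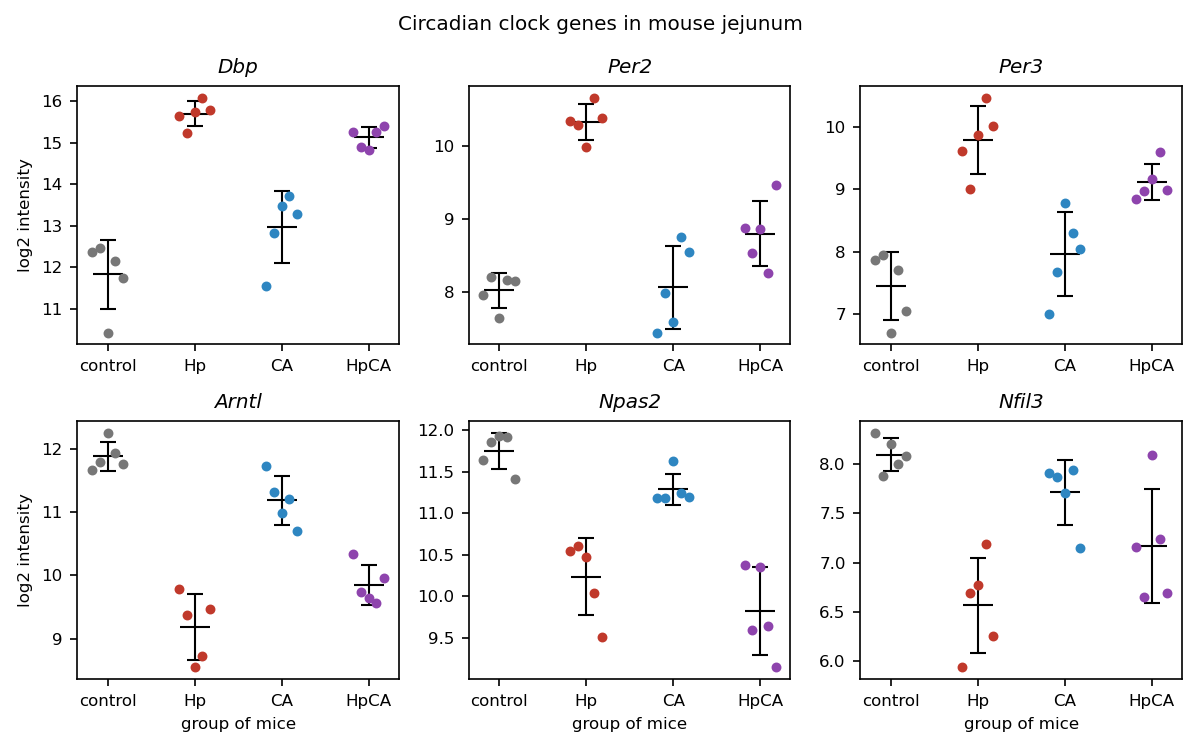
Log2 intensity of clock genes in jejunum, 1 point per mouse, with bars for the mean and SD of 5 mice per group. Dbp, Per2 and Per3 averaged higher and Arntl, Npas2 and Nfil3 lower in Hp than in control mice, and HpCA mice averaged 8.80 for Per2 against 10.3 in Hp mice.

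Among the largest falls were single genes of transport and metabolism, while the enterocyte list as a whole had a median of 0.15 over 29 members (adjusted p = 0.00074; adjusted p = 0.423 with an estimated correlation). Slc34a2, a phosphate transporter, fell by 3.62 (SE 0.69, adjusted p = 0.015), G6pc, the glucose-6-phosphatase of glucose release, by 2.91 (SE 0.42, adjusted p = 0.00094) and Slc17a4, an organic anion transporter, by 1.72. The call of Slc34a2 ended without Hp replicate 4 (adjusted p = 0.052). Angptl4, a PPAR target that inhibits lipoprotein lipase, fell by 2.70, and this call ended without control replicates 1, 3 or 4 or Hp replicates 3, 4 or 5 (adjusted p = 0.058, 0.090, 0.070, 0.060, 0.080 and 0.052).

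Several lists shifted down in the same comparison. PPAR alpha targets and fatty acid oxidation (24 measured) had 1 member that fell (adjusted p = 0.00024; adjusted p = 0.228 with an estimated correlation), and 6 fell and 1 rose when adjusted over the list alone. Among cytochrome P450 and other xenobiotic genes, 2 of 32 fell and 5 when adjusted over the list alone (adjusted p = 0.001; adjusted p = 0.423 with an estimated correlation). Tight junction and barrier genes had 2 of 14 past the threshold (adjusted p = 0.0002; adjusted p = 0.217 with an estimated correlation), and fry gave 0.018. Of these 2, Cldn8 lay below background in Hp mice and in all controls but replicate 5, so no change is given for it. Type I interferon response genes had a median of -0.42 over 22 members (adjusted p = 4.4e-05; adjusted p = 0.219 with an estimated correlation), of which 0 passed and 5 fell when adjusted over the list alone. Proliferation genes had a median of -0.38 over 26 members (adjusted p = 2e-06; adjusted p = 0.423 with an estimated correlation), none of which passed, such as Cdc20 at -0.82 (adjusted p = 0.25).

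In total 75 genes passed, 27 higher and 48 lower, and 1992 had an unadjusted p below 0.05, where 975 are expected by chance. Of the 75, 4 lay below background in both groups. Leaving out 1 array gave 41 genes without Hp replicate 3, 42 without Hp replicate 4 or control replicate 4, 43 without control replicates 2 or 3, and 120 without HpCA replicate 3. With the mean of the hybridisation controls as a covariate, chosen after seeing the data, the count was 41.

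In cinnamaldehyde mice infection raised mast cell genes as well. Mcpt1 rose by 8.77 ± 0.50 (adjusted p = 3.8e-10), and Mcpt2 and Cpa3, below background in CA mice, were at least 76.5-fold and at least 31.6-fold higher. Of the mast cell list 7 of the 18 mast cell genes rose, 10 when adjusted over the list alone (list adjusted p = 8.6e-17; adjusted p = 0.0291 with an estimated correlation). The list of alternatively activated macrophages, which type 2 cytokines induce, passed with 1 of 20 members that rose and 2 when adjusted over the list alone (adjusted p = 1.9e-06; adjusted p = 0.0291 with an estimated correlation). That member was Retnla, a secreted macrophage product, below background in CA mice and at least 3.05-fold higher in HpCA mice (adjusted p = 0.044). Its call held without Hp replicates 1, 2 or 4, CA replicate 5 or HpCA replicates 1 or 2 and ended without each of the other 14 arrays, with an adjusted p of at most 0.12. The mean of the macrophage list lay below the median of the negative controls on every jejunum array. The highest mean was 6.36, against 6.87 for those controls, on HpCA replicate 3. How much of the list's shift lies above background is therefore uncertain. G6pc fell by 3.34 (SE 0.42, adjusted p = 0.00021).

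Clock genes changed here as well, with 1 of 17 that rose, 2 that fell, and 7 and 3 when adjusted over the list alone (list adjusted p = 0.012; adjusted p = 0.303 with an estimated correlation). Dbp rose by 2.16 ± 0.36 (adjusted p = 0.0083), while Npas2 and Arntl fell by 1.46 and 1.34. The list's call ended without CA replicate 5 (adjusted p = 0.077) or HpCA replicates 1 (0.065) or 5 (0.057). The tuft cell list had a median of 0.83 with 0 members past the threshold and 2 when adjusted over the list alone (adjusted p = 1.6e-06; adjusted p = 0.303 with an estimated correlation).

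For 3 lists of the gut wall the call in cinnamaldehyde mice rests on the preset correlation, with 0 members past the threshold in each. Smooth muscle genes had a median of 0.97 over 19 members (adjusted p = 2.5e-07; adjusted p = 0.303 with an estimated correlation), including Cnn1, a muscle actin-binding protein, at 1.52 ± 0.71 (adjusted p = 0.42). Fibroblast and matrix genes had a median of 0.46 over 20 members (adjusted p = 4e-06; adjusted p = 0.303 with an estimated correlation). Endothelial genes had a median of 0.50 over 15 members (adjusted p = 4.3e-05; adjusted p = 0.257 with an estimated correlation), including the junction protein Pecam1 at 1.12 ± 0.25 (adjusted p = 0.082). Pecam1 passed without Hp replicate 4 (adjusted p = 0.022), CA replicate 4 (0.046) or HpCA replicate 1 (0.048). On CA replicate 4 the smooth muscle list averaged 9.91, where the other CA mice lay between 11.9 and 12.2. PPAR alpha genes fell in 1 of 24 (adjusted p = 0.00016; adjusted p = 0.303 with an estimated correlation), the same Angptl4, by 2.78, a call that ended without CA replicates 2, 3 or 4 or HpCA replicates 3 or 4 (adjusted p = 0.069, 0.11, 0.096, 0.087 and 0.10).

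In total 32 genes passed, 21 higher and 11 lower, with 2201 at an unadjusted p below 0.05, and 2 of the 32 lay below background in both groups. The count was 17 without CA replicate 2, 18 without CA replicate 3, 19 without HpCA replicate 4 or 5, 49 without CA replicate 5 and 69 without HpCA replicate 1, and the share of calls that were higher, 65.6%, was 51.4% after quantile normalization again and 38.6% after centring each array.

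The infection effects with and without cinnamaldehyde compared different mice, but each gene's variance came from the same fit of all jejunum arrays. Without HpCA replicate 3, for example, the count in mice without cinnamaldehyde went from 75 to 120. The effects shared 16 calls, 9 higher, 7 lower and 0 opposite. Independent lists would share 0.0291 higher and 0.0271 lower. Genes of small variance are favoured in both lists, so the lists were not independent and the gap to these values decides nothing. Of the 75 genes called without cinnamaldehyde, 71 had the same sign with it, and 28 of the 32 called with it had the same sign without it. Across genes, which are not independent replicates, the differences correlated with r = 0.403. The genes called in mice without cinnamaldehyde separated HpCA from CA mice by 2.82, and those called in cinnamaldehyde mice separated Hp from control mice by 3.82 (exact two-sided permutation p = 0.00794 each, the smallest possible; adjusted 0.0185 each).

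**Figure D3:**
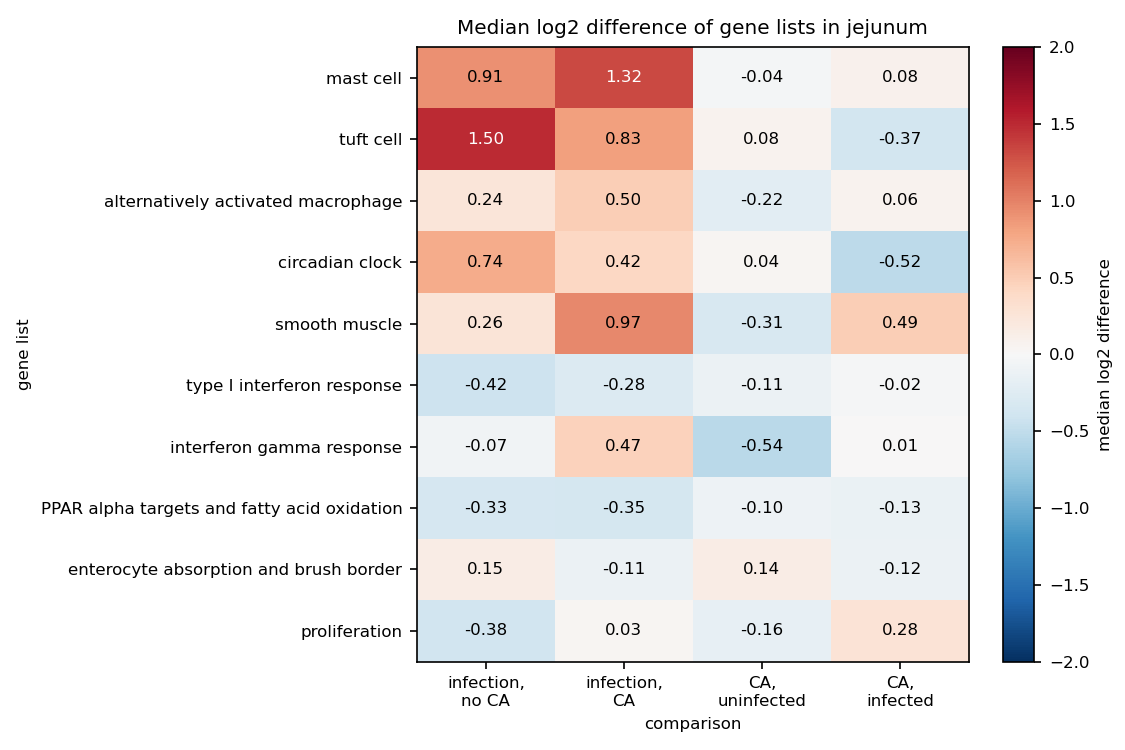
Median log2 difference over the measured members of 10 gene lists (vertical axis) in 4 jejunum comparisons (horizontal axis), coloured from -2 to 2. The mast cell list lies at 0.91 and 1.32 for infection without and with cinnamaldehyde, and at -0.04 and 0.08 for cinnamaldehyde without and with infection.

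Averaged over both diets, infection raised 9 of the 18 mast cell genes. Mcpt1 rose by 8.66 ± 0.35 (adjusted p = 3.5e-13), and 10 members rose when adjusted over the list alone (list adjusted p = 6.1e-21; adjusted p = 0.0224 with an estimated correlation). Tuft cell genes rose in 6 of 18 and in 15 when adjusted over the list alone (adjusted p = 1.2e-14; adjusted p = 0.114 with an estimated correlation), with Alox5ap at 1.70 ± 0.31 (adjusted p = 0.0053) and Dclk1 at 1.73 ± 0.39. The call of Dclk1 ended without control replicate 3 (adjusted p = 0.051). Retnla, below background in uninfected mice, rose (adjusted p = 0.009) as 1 of 2 alternatively activated macrophage genes that rose out of 20, 5 when adjusted over the list alone (adjusted p = 3.6e-06; adjusted p = 0.0224 with an estimated correlation). The mean of that list lay below the median of the negative controls on every jejunum array. Pla2g4c, a cytosolic phospholipase, rose by 5.80 ± 1.25 (adjusted p = 0.019).

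Among the clock genes 8 rose and 3 fell of 17, 11 and 3 when adjusted over the list alone (adjusted p = 9.6e-07; adjusted p = 0.0629 with an estimated correlation), led by Dbp at 3.01 and Arntl at -2.02 (adjusted p = 1.7e-07 and 1.2e-07). G6pc fell by 3.12 (adjusted p = 1.1e-06), and Slc34a2 and Angptl4 changed by -2.86 and -2.74 (adjusted p = 0.003 and 0.00033). Angptl4 was 1 of 5 PPAR alpha genes that fell out of 24, with 8 that fell and 1 that rose when adjusted over the list alone (adjusted p = 3.2e-06; adjusted p = 0.114 with an estimated correlation). Of 32 xenobiotic genes 4 fell, and 10 fell and 1 rose when adjusted over the list alone (adjusted p = 7.1e-06; adjusted p = 0.281 with an estimated correlation), among them Abcg2, an efflux pump, at -0.90 (adjusted p = 0.0041). Ocln, the tight junction protein occludin, fell by 0.63. It was 1 of 2 of the 14 barrier genes past the threshold, the other being Cldn8, which was above background only on control replicate 5, and 5 passed when adjusted over the list alone (adjusted p = 3.6e-05; adjusted p = 0.114 with an estimated correlation). In the type I interferon list 3 of 22 fell, 7 when adjusted over the list alone (adjusted p = 4.4e-06; adjusted p = 0.114 with an estimated correlation).

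Of those interferon genes, Ifit1 fell by 1.25 (adjusted p = 0.025), a call that ended without control replicates 1, 3 or 4, Hp replicate 2 or HpCA replicates 3 or 4, with adjusted p of at most 0.054. The other interferon calls, of Cmpk2 and Rsad2, each ended without 13 of the 20 arrays (adjusted p of at most 0.072 and 0.078). Rsad2 also lay below background in most groups. Smaller changes past the threshold included the cholesterol sensor Insig1 at 0.78, the glutathione peroxidase Gpx2 at 1.03, the death receptor Fas at -0.84 and the glycolytic regulator Pfkfb3 at -1.17. In total 306 genes passed, 115 higher and 191 lower, with 2779 at an unadjusted p below 0.05, and 19 of the 306 lay below background in all 4 groups. The count was 158 without control replicate 3, 191 without CA replicate 3, and 192, 195 and 198 without control replicates 2, 1 and 4, and 191 with the hybridisation controls as a covariate.

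Cinnamaldehyde in uninfected mice changed 0 genes past the threshold in limma, while 1474 had an unadjusted p below 0.05 and the other limma settings run all gave 0 as well. Genes of interferon gamma and antigen presentation were lower in sum: the interferon gamma response list had a median of -0.54 over 21 members (adjusted p = 1e-05; adjusted p = 0.475 with an estimated correlation), and MHC class II genes, which present antigen to T cells, a median of -0.70 over 10 (adjusted p = 0.00015; adjusted p = 0.475 with an estimated correlation). In each, 3 members were lower when adjusted over the list alone. Values that did not pass included H2-DMa, a peptide loader of class II molecules, at -1.34 ± 0.34 (adjusted p = 0.43), H2-Ab1 at -0.93, the guanylate-binding protein Gbp2 at -0.97 and the chemokine Cxcl10 at -0.99. The endothelium list had a median of -0.34 over 15 members, 2 of them lower when adjusted over the list alone (adjusted p = 0.00015; adjusted p = 0.475 with an estimated correlation), and macrophage and dendritic cell genes a median of -0.30 over 18 (adjusted p = 0.0023; adjusted p = 0.475 with an estimated correlation).

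The genes with the smallest p were P2rx7, an ATP-gated channel, at -1.30 ± 0.27 (adjusted p = 0.36), Trib1, a pseudokinase, at -1.30 ± 0.29 and Entpd1, an ATP-degrading ectoenzyme, at -0.68 ± 0.15 (adjusted p = 0.42 for both). In all 16 of the 44 lists passed, 1 higher and 15 lower, of which 0 held with an estimated correlation and 10 passed without control replicate 1. Centring each array shifted the median of all genes in this comparison by 0.11.

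Cinnamaldehyde in infected mice lowered 10 genes, raised 0, and gave 1648 at an unadjusted p below 0.05. Rasgef1b fell by 2.22 (SE 0.27, adjusted p = 0.00098) and the immediate early factor Fos by 2.12 (SE 0.32, adjusted p = 0.0049). Tppp, a microtubule-binding protein, fell by 1.79 (SE 0.24, adjusted p = 0.002). Fam102a fell by 1.14, and Rfx2, a cilia transcription factor below background in HpCA mice, was at least 1.17-fold lower. The clock repressors Per2 and Per1 fell by 1.54 and 1.43 and the clock-driven deadenylase Noct by 1.36, while the lysophosphatidic acid receptor Lpar3 and the cell cycle inhibitor Sfn changed by -1.198 and -0.99.

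Of 17 clock genes 2 fell, and 3 fell and 1 rose when adjusted over the list alone (adjusted p = 0.00033; adjusted p = 0.374 with an estimated correlation). Of 19 immediate early genes, which respond within minutes to stimuli, 1 fell and 3 when adjusted over the list alone (adjusted p = 0.00074; adjusted p = 0.374 with an estimated correlation), with Dusp1 at -1.13 (adjusted p = 0.25). Proliferation genes had a median of 0.28 over 26 members, 3 of them higher when adjusted over the list alone (adjusted p = 6.9e-05; adjusted p = 0.969 with an estimated correlation), including the kinase Cdk1 at 0.99 ± 0.30 (adjusted p = 0.33). Ribosomal protein genes had a median of 0.22 over 17 (adjusted p = 0.0013; adjusted p = 0.969 with an estimated correlation).

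The count was 6 without Hp replicate 1, 20 without CA replicate 5 and 35 without HpCA replicate 1, and 4 in a fit of only Hp and HpCA mice. The call of Per1 ended without Hp replicates 1 or 3 or HpCA replicate 4 (adjusted p = 0.070, 0.062 and 0.072). That of Noct ended without Hp replicates 1, 2 or 3 or HpCA replicates 2, 3 or 4 (0.11, 0.12, 0.068, 0.11, 0.067 and 0.12). That of Lpar3 ended without Hp replicates 1, 2 or 4 or HpCA replicates 2 or 4 (0.088, 0.068, 0.057, 0.077 and 0.094), and that of Sfn without Hp replicates 1, 2 or 3 or HpCA replicates 3, 4 or 5 (0.088, 0.055, 0.093, 0.060, 0.094 and 0.072).

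Averaged over infection, cinnamaldehyde lowered 4 genes and raised 0, with 1820 at an unadjusted p below 0.05. Trib1 fell by 1.35 (SE 0.20) and Rasgef1b by 1.27 (SE 0.19; adjusted p = 0.013 for both), Tppp by 0.99 and Entpd1 by 0.63 (adjusted p = 0.042 for both). In uninfected mice alone Rasgef1b and Tppp differed by only -0.33 and -0.18 (adjusted p = 0.83 and 0.91), so their averages come mostly from infected mice, while Trib1 and Entpd1 differed by -1.30 and -0.68 there. The immediate early genes Fos and Dusp1 differed by -1.18 (adjusted p = 0.055) and -1.01 (adjusted p = 0.084). Fos passed without HpCA replicates 1, 3 or 5 (adjusted p = 0.021, 0.043 and 0.034) and Dusp1 without Hp replicate 4 (0.048) or HpCA replicate 1 (0.038). Of their list, 3 of 19 members were lower when adjusted over the list alone, with 0 past the threshold over all genes (list adjusted p = 8.1e-05; adjusted p = 0.184 with an estimated correlation). The endothelium list had a median of -0.28 over 15 members, 3 of them lower when adjusted over the list alone (adjusted p = 0.00025; adjusted p = 0.453 with an estimated correlation).

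This count of 4 was 2 without control replicates 1, 2 or 4, Hp replicates 2 or 3, CA replicates 1 or 4 or HpCA replicates 2 or 4, and 7, 11, 14 and 34 without CA replicate 5, Hp replicate 4, HpCA replicate 3 and HpCA replicate 1. With the hybridisation controls as a covariate it was 0. The call of Entpd1 ended without 11 of the 20 arrays and that of Tppp without 13, among them each array whose absence left 2 calls, with adjusted p of at most 0.088 and 0.11.

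The interaction, which asks whether infection acted differently in cinnamaldehyde mice, gave 0 genes in limma, with 1245 at an unadjusted p below 0.05, 0 in the other limma settings run, and 1 without CA replicate 1. Values that did not pass included Rasgef1b at -1.89 ± 0.39, Tppp at -1.62 ± 0.34 and Per2 at -1.58 ± 0.35 (adjusted p = 0.38 for each), Arntl at 1.37 ± 0.33 (adjusted p = 0.43) and Dbp at -1.71 ± 0.51 (adjusted p = 0.70). Of 17 clock genes 2 were higher and 6 lower when adjusted over the list alone (list adjusted p = 0.0013; adjusted p = 0.685 with an estimated correlation), and fry's test for change in either direction gave 0.00026. MHC class II genes had a median of 0.83 over 10 members and proliferation genes 0.46 over 26 (adjusted p = 0.0013 and 3.5e-05; adjusted p = 0.685 with an estimated correlation for both). The median standard error of a gene was 0.31 here, against 0.22 between 2 groups. Centring each array shifted the median of all genes by -0.13 in this comparison.

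The infection signature, the 306 genes called in the average of both diets, differed by -0.03 between HpCA and Hp mice (exact two-sided permutation p = 0.944). It differed by 0.13 between CA and control mice (exact permutation p = 0.206) and by -0.16 as a difference of the differences (permutation p = 0.674). Leaving out HpCA replicate 1 or 2, Hp replicate 4 or CA replicate 5 turned the first value to 0.28, 0.17, 0.06 and 0.02. Without HpCA replicate 1 or 2 the difference of the differences was 0.14 and 0.02, and without Hp replicate 2 the second value was 0.22 (exact permutation p = 0.0238).

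In CMT93 cells cinnamaldehyde raised 8 genes and lowered 0, mostly genes of NRF2, the regulator of the response to electrophiles and oxidants. Gsta2, a glutathione transferase, rose from 6.05 ± 0.06 to 11.7 ± 0.12 (SD, n = 2 each), a difference of 5.65 ± 0.29 (SE, limma adjusted p = 0.00021). Hmox1, heme oxygenase 1, rose by 4.99 and Slc7a11, the cystine importer, by 4.98 (adjusted p = 0.00041 for both), and Gclc, which makes glutathione's precursor, by 3.47 (adjusted p = 0.0035). Of 30 measured NRF2 targets 6 rose, 17 when adjusted over the list alone (adjusted p = 8.3e-27; adjusted p = 0.275 with an estimated correlation). The AP-1 component Fosl1, the aldo-keto reductase Akr1b8, the esterase Esd and Gpx2 rose by 3.22, 2.78, 2.74 and 2.52.

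The list of the unfolded protein and ATF4 response had a median of 0.28 over 26 members (adjusted p = 0.0091; adjusted p = 0.777 with an estimated correlation), with Trib3 at 1.42 ± 0.31 (adjusted p = 0.46), and its call ended without CMT93 CA culture 1 (adjusted p = 0.078). In cells 1350 genes had an unadjusted p below 0.05. The count of 8 was 119 without control culture 1, 5 without CA culture 1 and 4 without CA culture 2, where the remaining culture was assumed to vary like the other group. The calls of Akr1b8, Esd and Gpx2 ended without CA culture 1 (adjusted p = 0.12, 0.12 and 0.28) or CA culture 2 (0.16, 0.20 and 0.20) and that of Fosl1 without CA culture 2 (adjusted p = 0.073).

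None of the 8 genes called in cells passed in the jejunum of cinnamaldehyde mice with limma, in either infection state. Hmox1 averaged 6.47 in CA and 6.63 in control mice, a difference of -0.16 with a 95% interval from -0.66 to 0.33, though it lay below background on 8 of these 10 arrays. Gclc differed by 0.08 with an interval from -0.38 to 0.53 and Gsta2 by -0.51 with an interval from -1.87 to 0.85, while Slc7a11 lay below background on 9 and Fosl1 on all 10 of these arrays. The signature of the 50 largest rises and 50 largest falls in cells differed by -0.28 between CA and control mice (exact permutation p = 0.00794, the smallest possible, adjusted 0.0185). Between HpCA and Hp mice it differed by -0.21 (exact permutation p = 0.0397, adjusted 0.0694). The first was -0.28 without CMT93 control culture 1 (exact permutation p = 0.0635), -0.13 without CMT93 CA culture 1 (exact permutation p = 0.175) and -0.12 without control culture 2 (exact permutation p = 0.0159). With only the 8 called genes it was -0.093 (exact permutation p = 0.476), and with the NRF2 list -0.074 (exact permutation p = 0.0635). Of its 50 rises 8 had passed in cells, and 16 lay below background on all 20 jejunum arrays. Of its 50 falls 0 had passed, 27 lay below background on all 20 jejunum arrays and 26 on all 4 cell arrays.

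**Figure D4:**
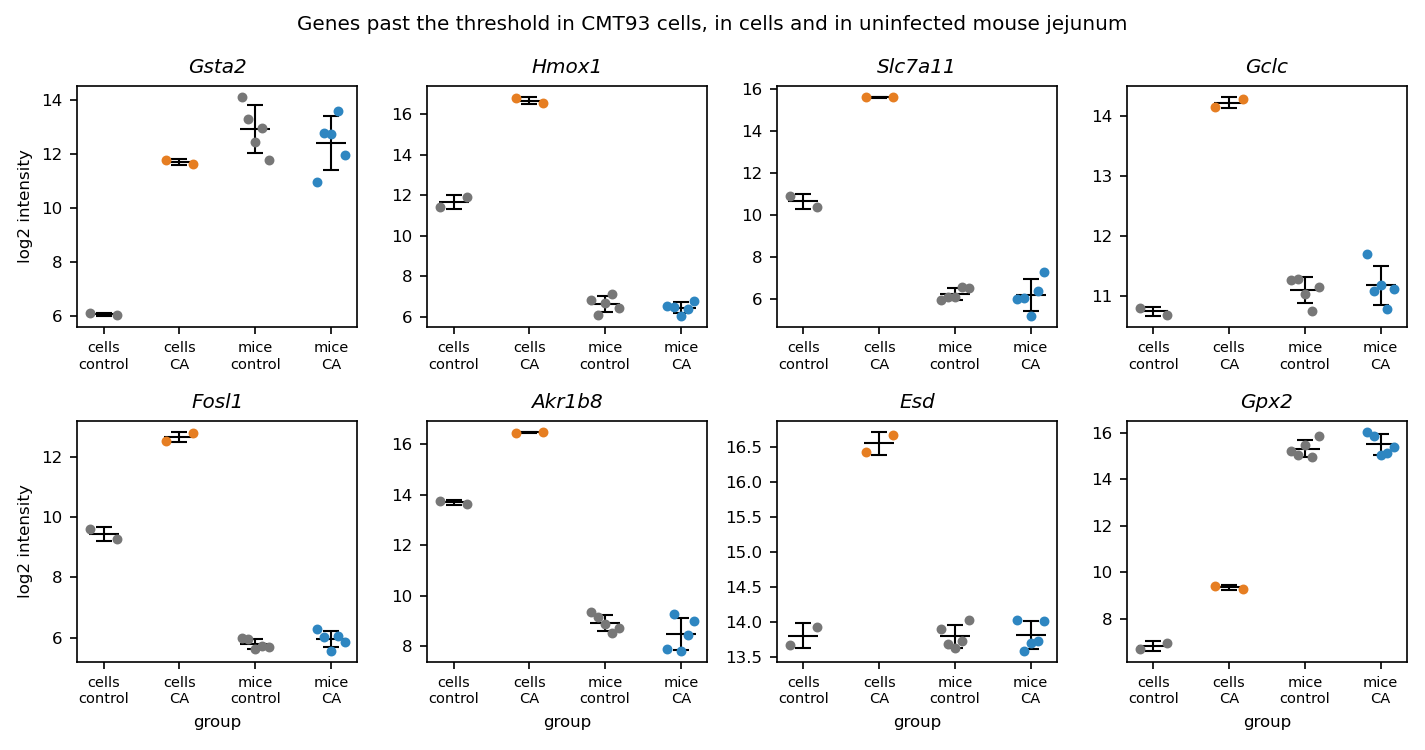
Log2 intensity of the 8 genes past the threshold in CMT93 cells, for cells (2 per group) and for jejunum of uninfected mice (5 per group), 1 point per sample with bars for the mean and SD. Hmox1 averaged 11.7 and 16.7 in control and treated cells and 6.63 and 6.47 in control and CA mice.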

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

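The tests of the splits of the samples were planned, and every other test of an explanation here was chosen only after the results were seen.

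Of 556 groups of 5 mice tested for a mouse far from the rest, 42 had one, where chance gives about 1 in 20. The array of HpCA replicate 3 held 11 of them, CA replicate 4 held 8 and control replicate 5 held 7. On HpCA replicate 3 the tuft cell list averaged 9.38 (7.04 to 7.65 in the other HpCA mice), Alox5ap 12.00 (8.95 to 9.64), Mcpt4 12.76 (7.82 to 8.87), Ms4a2 9.22, Tmem252 11.59 and P2rx7 9.36. The same mouse was low for the interferon gamma list at 8.92 (9.74 to 10.04 in the others), Gbp2 at 9.02, H2-Ab1 at 13.97, Hsph1 at 9.85 and Myc at 9.19. CA replicate 4 was low for the smooth muscle list at 9.91 (11.86 to 12.22 in the other CA mice), with Tagln at 11.35 and Cnn1 at 11.05, for the Paneth cell list at 13.78 with Mptx1 at 11.45, for the stem cell list at 8.65, for the enteric neuron and glia list at 4.97 and for Mcpt9 at 4.25, a value below background.

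Control replicate 5 was high for the bile acid list at 12.29 (8.72 to 9.20 in the other controls), the tight junction list at 12.57 and Cldn8 at 8.10. It was low for the enterocyte list at 15.64, the type I interferon list at 8.57, the eosinophil list at 5.48 and Slc3a2 at 15.78. CA replicate 5 stood apart for Ms4a2 at 5.33, Noct at 9.31, Fkbp1b at 4.57 and the median of the negative controls at 6.64, below which both Ms4a2 and Fkbp1b lay. Hp replicate 4 stood apart for H2-Ab1 at 13.73, Dusp1 at 13.23 and Cmpk2 at 10.36. Hp replicate 3 did so for Tppp at 10.63 and Esd at 13.83, and HpCA replicate 1 for Slc17a4 at 11.63 and the negative controls at 7.02. Single cases were the bile acid list on CA replicate 1 at 10.42, Npas2 on CA replicate 3 at 11.63, Cmpk2 on control replicate 1 at 11.65, Dab1 on control replicate 3 at 14.55 and Insig1 on Hp replicate 2 at 10.96.

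The infection effect differed between cinnamaldehyde and other mice for 12 lists by the interaction test at the preset correlation, and for 0 with an estimated correlation. The median differences were 1.63 for adipose tissue, 0.83 for MHC class II, 0.72 for smooth muscle, 0.63 for B and plasma cells, 0.49 for the interferon gamma response, 0.46 for proliferation, 0.44 for Paneth cells, 0.38 for stem cells, 0.38 for cholesterol synthesis, 0.22 for ribosomal proteins, -0.35 for enterocytes and -0.42 for the clock. The interferon gamma call ended without Hp replicate 4 (median 0.12, adjusted p = 0.14), and the B and plasma cell call without control replicate 4 (0.097) or CA replicate 3 (0.065). That of smooth muscle ended without Hp replicates 1 or 5 or CA replicate 4 (0.10, 0.056 and 0.15). The stem cell call ended without control replicate 2, Hp replicates 1 or 5, CA replicate 4 or HpCA replicate 4 (0.053, 0.058, 0.056, 0.39 and 0.16). The Paneth cell call ended without control replicates 2 or 5, Hp replicates 1 or 5, CA replicate 4 or HpCA replicates 3 or 4 (0.053, 0.099, 0.21, 0.26, 0.93, 0.16 and 0.13). The adipose call ended without control replicates 1 or 3, Hp replicates 1, 4 or 5, CA replicate 5 or HpCA replicates 2, 4 or 5 (0.087, 0.064, 0.058, 0.071, 0.12, 0.082, 0.053, 0.094 and 0.10).

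Among the 2634 transcript clusters without a gene symbol, which the comparisons above leave out, 3 passed for infection without cinnamaldehyde, 2 for infection in cinnamaldehyde mice, 23 for infection averaged over diets, 2 for cinnamaldehyde in infected mice and 6 for cinnamaldehyde averaged over infection.

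Each count of genes was set against 100 splits of the same arrays into groups of the same sizes, the real one included. Only the real split, 1 of the 100, gave as many genes for infection without cinnamaldehyde (75 genes, at most 2 in another split). The same held for infection in cinnamaldehyde mice (32, at most 20) and for infection averaged over diets (306, at most 0). A share of 1 in 100 is the smallest these splits allow, and the number of comparisons was not adjusted for. Chance is thus argued against for these counts but not excluded. For cinnamaldehyde averaged over infection 3 splits gave as many (4 genes, at most 6), and for cinnamaldehyde in infected mice 4 did (10, at most 62). For these 2 the real count lies within the range of the other splits, and the number of comparisons was not adjusted for, so chance is not excluded. The split with 62 genes gave several times the real count, and the reason was not tested. For cinnamaldehyde in uninfected mice (0 genes, at most 9 in another split) and the interaction (0, at most 2) all 100 splits give as many whatever the data, so the splits decide nothing there.

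The clock genes changed with infection in mice without cinnamaldehyde. With the smooth muscle list as a covariate 10 of the 10 called clock genes still passed, 1 of which, Tef, lay below background. That list averaged 12.2 (SD 1.22) in Hp and 11.9 (SD 0.19) in control mice, so the covariate could remove little of a group difference. Mast and tuft cell lists, which rose, were not used as covariates, so the cell mix of the gut wall stays open. Unequal labelled target is argued against as the whole cause, since 9 of the 10 still passed with the hybridisation controls as a covariate. The call of Nr1d2 ended there because its difference went from 1.05 ± 0.21 to 1.00 ± 0.23, a smaller value with a larger error (adjusted p = 0.085). A difference in the time of day of sampling stays open beside an effect of infection on the clock: the phase score, defined after the values were seen as the mean of Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per1, Per2, Per3, Ciart, Usp2 and Bhlhe41 minus that of Arntl, Npas2, Clock, Cry1 and Nfil3, differed by 2.69 between Hp and control mice, and with no sampling times used here these cannot be told apart.

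NRF2 targets rose in CMT93 cells, while their mean in jejunum differed by -0.07 between CA and control mice. Spread between mice is argued against as what hides a rise of that size, since the highest CA mouse lay 0.062 above the lowest control mouse, against 1.29 between the nearest treated and control cultures. Signal below background stays open for 3 of the 8 genes, Slc7a11, Hmox1 and Fosl1, which lay below the negative controls on 9, 8 and 10 of the 10 control and CA arrays, while the other 5 lay below on 0. In a fit of all 24 arrays, 7 of these 8 differed more in cells than in jejunum, and Gpx2 did not pass (adjusted p = 0.11). The 8 were chosen because they passed on the same cell arrays, which favours a larger rise in cells, so this fit adds no support. For Slc7a11, Hmox1 and Fosl1 the jejunum side of that difference was also largely set by the background. Dose, time, route and cell types differed together, so the gap of 1.502 in the list mean cannot be assigned to any of them.

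The array of CA replicate 5 stood apart from the other jejunum arrays. Less labelled target from this sample is a candidate explanation, since its hybridisation controls lay 0.69 above the highest of the other 19 and the spread of its values (interquartile range) 0.24 below the lowest of them. The poly-A controls, a further set of spike-in controls, averaged 6.09 on this array. The lowest of the other 19 was 7.46, on Hp replicate 5. What set the poly-A controls low on this array was not tested. For tissue of another kind, 0 of 20 cell type lists lay above the range of the other arrays. The enteroendocrine list at 8.87 and the alternatively activated macrophage list at 5.23 lay below it (lowest others 9.07 and 5.27). That range includes infected mice and is wide, and the values of this array are compressed, so the count could hardly show such tissue and decides little. An infected mouse under an uninfected label is argued against, since its mast cell list lay -1.23 from the lowest infected mouse. These are technical explanations, and no biological one was tested for this array.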

How the results depend on the processing

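The covariates for clock phase and hybridisation controls, the run without the 2 arrays of strongest hybridisation controls and the narrower cell signatures were chosen only after the results were seen. Of the values for named genes under the alternatives, 4464 kept direction and side of the threshold, 243 no longer passed, 74 newly passed and 10 turned; for lists these were 2753, 495, 0 and 8, and for signatures 156, 22, 1 and 8. Of the counts of genes 193 stayed within 1.5 times the main count and 78 did not, and of the counts of lists 185 and 29. Of 89 calls of named genes, 12 held under every alternative, clock phase included. Clock phase as a covariate gave 61 of the 243 named gene values that no longer passed and all 10 that turned. As said below, it also removes infection, so the 12 say little about how stable the infection calls are. Cinnamaldehyde in uninfected mice gave 0 genes in all limma runs and the interaction 0 to 1. Counts without single arrays ran from 41 to 120 for infection without cinnamaldehyde (main 75), 17 to 69 in cinnamaldehyde mice (32), 158 to 431 averaged (306), 6 to 35 for cinnamaldehyde in infected mice (10), 2 to 34 averaged (4) and 4 to 119 in cells (8). List counts ran, in the same order, from 18 to 22, 21 to 26, 20 to 25, 5 to 15, 2 to 14 and 3 to 6, from 10 to 19 for cinnamaldehyde in uninfected mice and 9 to 14 for the interaction. Infection without cinnamaldehyde gave 203 genes with array weights, 128 with trend and robust settings, 126 with only its 2 groups, and 118, 183, 1 and 41 with smooth muscle, enterocytes, clock phase and hybridisation controls as covariates. In cinnamaldehyde mice these were 50 with weights, 11 with 2 groups, and 13, 21 and 3 with the first 3 covariates (14 lists with smooth muscle). The averaged infection count was 161, 555, 2 and 191 with the 4 covariates. Clock phase separates all infected from all uninfected mice, so that covariate also removes infection. Cinnamaldehyde in infected mice gave 17 with trend and robust settings, 16 with all 24 arrays and 4 with 2 groups. It gave 20 with the genes below the median left out, 6 with enterocytes and 5 with clock phase, 2 of these 5 among the main calls. Its average gave 2 after quantile normalization or centring, 16 and 20 with fewer dim genes, 18 with unnamed clusters, 22 with trend and robust settings, 14 with weights, 10 with all arrays, 17, 13, 8 and 0 with the 4 covariates and 11 without the 2 arrays of strongest hybridisation controls. Cells gave 15 with fewer dim genes, 23 with trend and robust settings and 32 with all 24 arrays. Lists for cinnamaldehyde in uninfected mice were 10 after quantile normalization and 9 with fewer dim genes, and 5 for its average. With an estimated correlation 2 lists passed in each infection comparison and 0 elsewhere, and with fry 3, 2 and 9 and 0 elsewhere. The replicate number as a block gave 21 genes for infection in cinnamaldehyde mice, 2 for averaged cinnamaldehyde and 16 in cells. The numbers do not pair the mice: same-numbered mice deviated together with a mean r of -0.0176, against 0.00474 for others, 5 of 30 pairs exceeded 0.1, and 3 of 20 mice correlated best with their own number. Permuting within such a block left 2.82, 3.82, -0.28 and -0.21 with an exact p of 0.0625, 0.0625, 0.0625 (the smallest possible) and 0.1875. Signatures without single arrays ran from -0.32 to 0.28 (HpCA minus Hp), 0.021 to 0.24 (CA minus control), -0.43 to 0.14 (difference of both), 1.93 to 4.10 and 2.47 to 5.91 across diets, and -0.33 to -0.12 and -0.29 to -0.13 for the cell signature. The infection signature of HpCA minus Hp was 0.0083 with fewer dim genes and 0.013 with 50 genes a side. The cell signature was -0.093 and -0.13 with the 8 called genes (exact p = 0.476 and 0.516), -0.074 and -0.069 with NRF2 targets (exact p = 0.0635 and 0.333), and -0.28 for HpCA minus Hp with fewer dim genes (exact p = 0.0635). With smooth muscle as covariate the smooth muscle list turned to 0.0026, -0.042, 0.0079 and -0.013 (cinnamaldehyde uninfected, infection in cinnamaldehyde mice, interaction, averaged infection), the neuron and glia list to 0.014 and 0.022 and the Paneth list's interaction to 0.0093. Those values are near 0 by construction for the smooth muscle list. Without single arrays that list ran from -0.47 to 0.11 for cinnamaldehyde in uninfected mice, turning without CA replicate 4. With clock phase, Dbp turned to -0.58, -0.21, 0.37 and -0.40, Per3 to -0.96, Slc34a2 to 1.71 and 1.23, Tmem252 to 0.52 and Rsad2, below background in 3 groups, to 0.23 and 0.14. For the other counts and turned values the cause was not tested. Genes below the negative controls have only bounds, whichever setting is used.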

Other observations

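The genes and relations described here, and all tests of them, were chosen only after values were seen.

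Averaged over both diets, infection also raised single genes outside the lists, with no list or test of a shared theme. Gasdermin C genes, which encode pore-forming proteins of the epithelium, rose together: Gsdmc by 1.98, Gsdmc2 by 2.25, Gsdmc3 by 2.16 and Gsdmc4 by 2.17 (limma adjusted p = 0.022, 0.021, 0.036 and 0.013). These paralogs are close in sequence, so it is uncertain that the probes tell them apart. None of the 4 passed within a single diet, where Gsdmc4 had the smallest adjusted p, 0.17 without and 0.18 with cinnamaldehyde. Serpina3n, a protease inhibitor, rose by 2.36 (adjusted p = 0.0032) and Slc13a1, a sulfate transporter, by 1.85 (adjusted p = 0.037). Neither passed within a single diet. Without and with cinnamaldehyde the adjusted p was 0.10 and 0.089 for Serpina3n. Slc13a1 differed by 2.64 without and 1.07 with cinnamaldehyde (adjusted p = 0.074 and 0.54). In the average of both diets Csf2rb rose by 1.21, Rac2 by 1.17 and Cd34 by 1.03. Mast cells, whose list rose, also express these, and whether they come from them was not tested.

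Single genes picked from the falls of the same comparison, with no list or test of a shared theme, follow. Mlxipl, a sugar-sensing transcription factor, changed by -0.66 and its targets Txnip and Arrdc4 by -0.40 and -0.68 (adjusted p = 0.011, 0.037 and 0.003). The sterol exporters Abcg5 and Abcg8 changed by -0.54 and -0.89, the receptors Erbb2, Erbb3 and Insr by -0.59, -0.95 and -0.48, and Dio1, which activates thyroid hormone, by -1.205 (adjusted p = 0.008).

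A hypothesis from the clock genes is that cinnamaldehyde made the shift with infection smaller. The phase score differed by 2.69 between Hp and control mice and by 1.44 between HpCA and CA mice (exact permutation p = 0.00794 each, the smallest possible). It also differed by 0.53 between CA and control mice (exact permutation p = 0.0635) and by -0.73 between HpCA and Hp mice (exact permutation p = 0.0159), so uninfected and infected mice both added to the value that follows. The difference of these differences was -1.26 (permutation p = 0.00079), and lay between -1.41 and -1.11 without single arrays. Without Tef, Hlf, Ciart and Bhlhe41, each below background in at least 1 group, it was -1.46 (permutation p = 0.00095). The score was defined after these genes were seen to differ, so its p restates that observation and decides nothing. The planned interaction test gave 0 genes. There the clock list passed at the preset correlation and in fry's test for change in either direction, as given above. With an estimated correlation camera gave an adjusted p = 0.685, but it tests a shift in 1 direction, where rises and falls cancel. Sampling times were not used either, so the hypothesis stays open.

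Across the 10 infected mice, deviations of the tuft cell list from the group means were set against those of 4 other lists. With the alternatively activated macrophage list, r was 0.85 (permutation p = 0.00156, adjusted 0.00624) and rho 0.733 (permutation p = 0.0271). Without HpCA replicate 3 and Hp replicate 4, the 2 mice farthest from the median, r was 0.52 (permutation p = 0.132). The value was smaller but still positive, so whether the relation holds without those 2 mice cannot be told. The mean of the macrophage list also lay below the median of the negative controls on every infected mouse's array. With the interferon gamma list r was -0.73 (permutation p = 0.0305, adjusted 0.0610; rho -0.527, p = 0.150) and 0.49 without the same 2 mice (permutation p = 0.322), so its sign turned. With smooth muscle r was 0.68 (permutation p = 0.0534, adjusted 0.0713; rho 0.661, p = 0.0593) and 0.38 without them (permutation p = 0.498). With the mast cell list r was 0.60 (permutation p = 0.0965, adjusted 0.0965, with rho 0.576, p = 0.102) and 0.55 without them (permutation p = 0.00388). With those 2 mice included, r was -0.38 within Hp and 0.98 within HpCA mice. Hp replicate 4 had the highest tuft cell mean of the Hp mice, 9.63, and their lowest mast cell mean, 7.22. Within those groups r was 0.85 and 0.86 for the macrophage list, -0.59 and -0.996 for interferon gamma, and 0.74 and 0.62 for smooth muscle.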
